A study of Mus musculus with 12 samples.

How the data were processed

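Total RNA was taken from the left ventricle of 12 mice with RNeasy columns, and 3 µg per sample was turned into biotin-labelled cRNA and hybridised to Affymetrix arrays, 1 array per mouse, per the labels' protocols. The labels give 4 groups of 3 mice: a sham at 4 weeks (sAB), aortic banding for 4 weeks (AB), a sham followed by debanding (sDB3) and banding followed by debanding with 3 days of recovery (DB3). Replicate numbers name the arrays in accession order, and the labels give them no shared animal, litter or batch. The authors' values are log2 signals per probe set, deposited as 1 table of the 12 arrays. GCRMA made them, per the submitters' processing notes. Its version, its settings and whether the 12 arrays were normalized in 1 run are not given in the sources used here. The log2 scale was checked on the range of the values. A common floor held 29.1% to 31.6% of probe sets on each array, so that the fold of a gene near it is compressed. Scanner files, detection calls and scan dates were not used here. No further normalization was applied in the main analysis.

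Probe sets were named through the platform annotation. Of the probe sets, 64 are controls, 34945 carry 1 gene symbol, 932 several and 9160 none. Those with several or none were left out. Symbols were updated by gene ID through the RefSeq gene table, where 34741 of those with 1 symbol were found. A probe set was tested where its log2 value was above 4 on at least 3 of the 12 arrays (17817 probe sets), and each gene was represented by its probe set with the highest mean over all 12 arrays, which gave 10435 genes. Of these, 4608 had more than 1 such probe set, and in AB against sAB 48 genes had probe sets passing in both directions. No genome build is named in the sources used here, so no coordinates are given.

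Differences between group means were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend or robust moderation) in 1 model of the 4 groups. The model follows the series' description of a per-gene analysis of variance with sham as control. It had 8 residual and 2.68 prior degrees of freedom. The comparisons were AB against sAB, DB3 against sDB3, the difference of these effects, sDB3 against sAB and DB3 against AB, plus an F test over the 4 groups. AB against sDB3 was added after the data were seen. P-values are two-sided and adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. An exact permutation test of 3 against 3 arrays cannot go below 0.1, so calls rest on the spread pooled over genes and groups. The spread covers differences between mice of these groups. Where comparisons share arrays, overlaps and correlations are given beside 20 simulations of unchanged groups.

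The rules by which the report names genes, the gene lists and the alternatives, except those given below as added after the data were seen, were fixed before the data were examined. Genes named are, by rule, those with the largest rise and fall among genes past the threshold whose groups do not overlap. There are 10 and 10 of them, and 5 and 5 for sDB3 against sAB and DB3 against AB. The overlap condition was not used for the difference of effects. To these were added 12 genes chosen for this tissue (Nppa, Nppb, Myh7, Myh6, Acta1, Atp2a2, Col1a1, Col3a1, Col8a1, Postn, Ccn2 and Timp1) and up to 4 members of each list with the largest change. The 32 lists cover hypertrophy, contraction, ion channels, matrix, metabolism, stress, clock and signalling genes and markers of other cell types that a ventricular sample can hold. The 27 lists with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation, fry and a run without the dim filter were the alternatives. With an estimated correlation no list passed in AB against sAB, DB3 against sDB3, the difference of effects, sDB3 against sAB or DB3 against AB (2, 4, 3, 2 and 5 lists at an unadjusted p under 0.05), and 1 passed in AB against sDB3. Fry asks whether the genes of a list move one way on balance, without comparing them with other genes.

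The gene test was tested on simulated data that used the real genes' means and spreads with 200 genes changed by 0.5 or 1 log2 units, 100 of each. Of the changes of 0.5 it recovered 59% in AB against sAB, 58% in DB3 against sDB3, 32% in the difference of effects, 54% in sDB3 against sAB and 64% in DB3 against AB. Of the changes of 1 it recovered 87%, 90%, 71%, 87% and 91%, in the same order. False calls made up 5.19%, 4.52%, 7.21%, 4.08% and 3.12% of the calls, which is above the threshold of 5% in AB against sAB and in the difference of effects. Alternatives to the main settings were no dim filter, a filter at log2 above 6, the mean of a gene's probe sets, every probe set tested, quantile normalization and centring each array on its median. Others were fits of only the groups compared, an unmoderated analysis of variance, eBayes with trend and robust moderation, array weights, a 1.5-fold minimum, an adjusted p of 0.1 and leaving out each array in turn. Added after the data were seen were fits without the sAB arrays, sDB3 as the control of AB, and Myl7 as a covariate for Nppa. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.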

Results

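Gene expression was measured in the left ventricular myocardium of 12 male C57BL/6 mice, 1 array per mouse, in 4 groups of 3. Mice of the AB group had a band placed around the aorta, which raises the load on the left ventricle, and were studied 4 weeks later. Mice of the DB3 group had the same banding, the band was removed, and the heart was studied 3 days after this debanding. The sAB group is the sham of the AB group. The sDB3 group, labelled as a sham procedure followed by debanding, is the sham of the DB3 group. The initial operation was at 7 weeks of age. The deposited values are log2 signals of an oligonucleotide array, and 10435 genes were tested after dim probe sets were left out. Between 42.4% and 43.1% of probe sets lay above a log2 value of 4 on each array. The number of arrays, 3 per group, limits the precision of every difference. Across probe sets, which are not independent replicates, arrays of 1 group correlated at 0.9955 to 0.9983 and arrays of different groups at 0.9933 to 0.9969, ranges that overlap.

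The sAB arrays stood apart on a control that carries no mouse RNA. BioC, a bacterial transcript added to the hybridisation mix, had a mean log2 signal over its probe sets of 10.35 ± 0.18 (SD, n = 3) on the sAB arrays. The means were 8.41 ± 0.17 on the AB, 8.39 ± 0.18 on the sDB3 and 8.39 ± 0.065 on the DB3 arrays. The lowest sAB array lay 1.55 log2 units above the highest of the other 9. For the other spiked controls the sAB mean minus the mean of the other 9 arrays was 0.26 for BioB, -0.21 for BioD and -0.32 for Cre. Of the genes tested, 1360 (13%) had all 3 sAB arrays above or below all other 9, where chance gives 0.909%. That count was 1047 for AB, 807 for sDB3 and 563 for DB3. BioC splits the arrays exactly as sAB against the rest, so batch and group cannot be told apart in any comparison that uses sAB. AB was therefore also set against sDB3, a comparison added after the data were seen. These arrays share 1 BioC level but differ in the second operation and the 3 days.

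**Figure D1:**
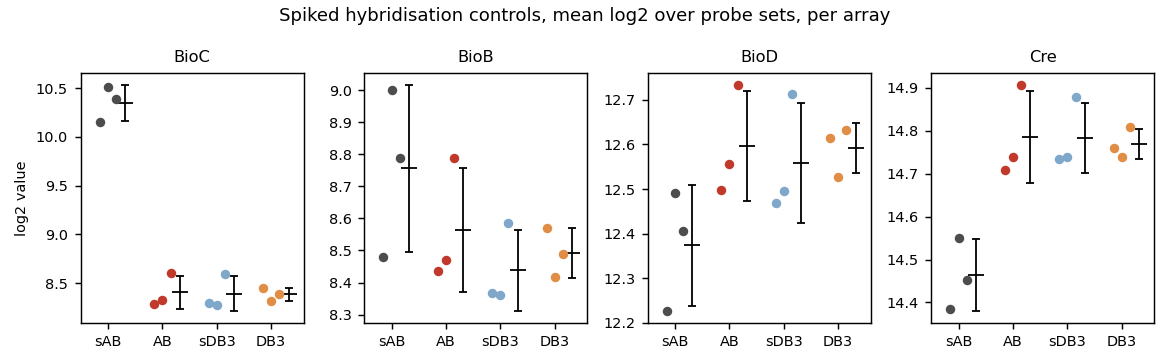
Log2 signal of the 4 spiked controls (vertical axes) on each of the 12 arrays by group (horizontal axes), where points are arrays and the black mark and bar give the mean and SD of 3. On BioC the 3 sAB arrays lie between 10.15 and 10.51 and the other 9 between 8.28 and 8.60.

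The comparison of AB with sAB asked what 4 weeks of pressure overload change. Genes of the fetal and hypertrophic programme of the ventricle were higher in AB. Myh7, the slow myosin heavy chain that the adult mouse ventricle largely replaces with Myh6, rose 8.95-fold (log2 difference 3.16 ± 0.25, SE, n = 3 per group, limma adjusted p = 5.06e-05). Nppa, which encodes atrial natriuretic peptide, rose 5.26-fold (2.39 ± 0.16, adjusted p = 1.38e-05). Acta1, skeletal alpha-actin, rose 2.48-fold (1.31 ± 0.21, adjusted p = 0.00228) and Nppb, B-type natriuretic peptide, 1.77-fold (0.82 ± 0.19, adjusted p = 0.0126). Of 16 measured hypertrophy-associated genes, 13 rose and 0 fell (14 and 0 adjusted over the list alone). The hypertrophy-associated genes list had a median log2 difference of 1.28 and lay higher by camera (adjusted p = 9.45e-11, adjusted p = 0.129 with an estimated correlation). Among its members the homeobox gene Meox1 rose by 1.86 and Frzb, a secreted Wnt inhibitor, by 1.62. Other large rises were those of Cnksr1, a scaffold of Ras signalling (2.57 ± 0.19), and Dio2, the deiodinase that activates thyroid hormone (2.29 ± 0.42). Lman1l rose by 2.59 ± 0.20 and was dim outside AB, where the background compresses its fold. Myh6 (-0.14 ± 0.059, adjusted p = 0.11), which lies at the top of the scale in every group, and Atp2a2, the calcium pump of the sarcoplasmic reticulum (-0.034 ± 0.061, adjusted p = 0.743), did not pass. Calls lost without 1 array were those of Nppb (without AB replicate 2, adjusted p up to 0.0506).

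By camera several lists of extracellular matrix genes lay higher in AB. Cilp, a matrix protein, rose by 2.81 ± 0.35, the thrombospondin Thbs4 by 2.56 ± 0.33, the matricellular Ccn2 by 2.13 ± 0.34 and Postn, periostin, by 1.91 ± 0.34, with adjusted p-values of at most 0.00351. Of 36 measured matrix glycoproteins and proteoglycans, 17 rose and 0 fell (19 and 0 adjusted over the list alone). The matrix glycoproteins and proteoglycans list had a median log2 difference of 0.61 and lay higher by camera (adjusted p = 4.69e-07, adjusted p = 0.398 with an estimated correlation). Of 15 measured other collagens, 10 rose and 0 fell (12 and 0 adjusted over the list alone). The other collagens list had a median log2 difference of 0.82 and lay higher by camera (adjusted p = 2.09e-07, adjusted p = 0.374 with an estimated correlation). Col8a1 rose by 1.86 ± 0.20 and Col15a1 by 1.70. Of 6 measured fibrillar collagens, 1 rose and 0 fell (4 and 0 adjusted over the list alone). The fibrillar collagens list had a median log2 difference of 0.67 and lay higher by camera (adjusted p = 0.0457, adjusted p = 0.675 with an estimated correlation). The fibrillar member was Col1a1 (1.76 ± 0.47, adjusted p = 0.025), whose call was lost without sAB replicate 1, sAB replicate 2 or AB replicate 3 (adjusted p up to 0.0995). Col3a1 (0.51 ± 0.41, adjusted p = 0.418) and Timp1, an inhibitor of matrix proteases (1.14 ± 0.54, adjusted p = 0.167), did not pass. Of 18 measured collagen processing and crosslinking genes, 7 rose and 0 fell (10 and 0 adjusted over the list alone). The collagen processing and crosslinking list had a median log2 difference of 0.22 and lay higher by camera (adjusted p = 0.000984, adjusted p = 0.398 with an estimated correlation). P3h2, a prolyl hydroxylase, rose by 1.13 and Loxl3, a lysyl oxidase relative, by 0.93. Of 33 measured TGF-beta and BMP signalling genes, 9 rose and 0 fell (10 and 0 adjusted over the list alone). The TGF-beta and BMP signalling list had a median log2 difference of 0.32 and lay higher by camera (adjusted p = 0.00197, adjusted p = 0.398 with an estimated correlation). Ltbp2, which belongs to the latent TGF-beta binding proteins, rose by 2.37 ± 0.34, the growth factor Tgfb2 by 2.14 ± 0.20 and Tgfb1 by 0.98. Fibroblast markers had 2 higher and 1 lower of 16 members and did not pass camera (adjusted p = 0.906).

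By camera the fatty acid, respiratory chain and channel lists lay lower in AB, the last 2 with few members passing. Acot1, a cytosolic acyl-CoA thioesterase, differed by -1.81 ± 0.26, the mitochondrial carnitine carrier Slc25a20 by -0.74 and the thiolase Acaa2 by -0.73. Of 31 measured fatty acid oxidation and transport genes, 0 rose and 15 fell (0 and 17 adjusted over the list alone). The fatty acid oxidation and transport list had a median log2 difference of -0.26 and lay lower by camera (adjusted p = 6.04e-06, adjusted p = 0.398 with an estimated correlation). Of 55 measured respiratory chain and citrate cycle genes, 0 rose and 8 fell (0 and 7 adjusted over the list alone, 0 and 14 after median centring). The respiratory chain and citrate cycle list had a median log2 difference of -0.10 and lay lower by camera (adjusted p = 1.75e-05, adjusted p = 0.398 with an estimated correlation). Idh3a of the citrate cycle differed by -0.27. Of 13 measured potassium and sodium channels, 1 rose and 4 fell (1 and 4 adjusted over the list alone). The potassium and sodium channels list had a median log2 difference of -0.39 and lay lower by camera (adjusted p = 0.0134, adjusted p = 0.374 with an estimated correlation). The potassium channel genes Kcnj3, Kcnj5 and Kcnv2 differed by -0.79, -0.74 and -0.68, with Kcnv2 dim in AB. The other largest falls were in Retnla (-2.35 ± 0.72), Efemp1, a matrix fibulin (-2.16 ± 0.35), the receptor kinase Ret (-2.03) and the water channel Aqp4 (-1.86). Further ones were in the calmodulin-binding Pcp4 (-1.84), Fbp2, muscle fructose-bisphosphatase (-1.69), Cenpf, a kinetochore protein (-1.62), the orphan receptor Gpr22 (-1.58) and Tbc1d10c (-1.57). Aqp4 and Pcp4 were dim outside sAB. A fit without 1 array ended the calls of Idh3a (without sAB replicate 1 or AB replicate 2, adjusted p up to 0.0765) and Retnla (10 arrays, adjusted p up to 0.146).

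Lists of vessel cell markers and immediate early genes lay higher in AB than in sAB and the macrophage list lower, and of these only the endothelial list also passed against sDB3 (camera adjusted p = 0.0159, adjusted p = 0.0882 with an estimated correlation). Of 20 measured endothelial markers, 6 rose and 0 fell (6 and 0 adjusted over the list alone, 3 and 0 after median centring). The endothelial markers list had a median log2 difference of 0.21 and lay higher by camera (adjusted p = 0.021, adjusted p = 0.252 with an estimated correlation). Robo4 and Tie1, endothelial receptors, rose by 0.68 and 0.54. Of 14 measured smooth muscle and pericyte markers, 6 rose and 1 fell (7 and 1 adjusted over the list alone). The smooth muscle and pericyte markers list had a median log2 difference of 0.24 and lay higher by camera (adjusted p = 0.0457, adjusted p = 0.398 with an estimated correlation). Cspg4 and Notch3, pericyte genes, rose by 1.07 and 0.60. Of 22 measured immediate early genes, 5 rose and 0 fell (5 and 0 adjusted over the list alone). The immediate early genes list had a median log2 difference of 0.37 and lay higher by camera (adjusted p = 0.0457, adjusted p = 0.652 with an estimated correlation). Egr2 and Myc, transcription factors, rose by 1.42 and 1.21, with Egr2 dim in sAB. Of 26 measured monocyte and macrophage markers, 1 rose and 0 fell (1 and 0 adjusted over the list alone). The monocyte and macrophage markers list had a median log2 difference of -0.30 and lay lower by camera (adjusted p = 0.0285, adjusted p = 0.931 with an estimated correlation). The single macrophage gene that passed was Cx3cr1, at 0.91. The other lists did not pass camera, given here with their higher and lower members. They were glycolysis and glucose uptake (5 and 0 of 20, adjusted p = 0.115), interferon response (0 and 0 of 24, adjusted p = 0.256), endoplasmic reticulum stress and protein folding (6 and 7 of 27, adjusted p = 0.302) and matrix proteases and inhibitors (6 and 1 of 27, adjusted p = 0.437). Next came ubiquitin ligases, proteasome and autophagy (4 and 3 of 32, adjusted p = 0.66), atrial markers (0 and 1 of 8, adjusted p = 0.786), blood markers (0 and 0 of 5, adjusted p = 0.803) and adult cardiac contraction and calcium handling (4 and 2 of 22, adjusted p = 0.803). The last were circadian clock (1 and 0 of 18, adjusted p = 0.867), acute phase and wound response (0 and 0 of 19, adjusted p = 0.867), epicardial and mesothelial markers (0 and 0 of 5, adjusted p = 0.89), cell cycle (0 and 0 of 12, adjusted p = 0.985) and glucocorticoid and fasting response (2 and 0 of 17, adjusted p = 0.998). Neutrophil, lymphocyte and thymus markers (2 measured each) and skeletal muscle and adipose markers (4 each) were too few to test. The muscle light chain Myl1 rose (0.88) and Mylpf fell (-0.45). When 1 array was left out, calls ended for Mylpf (10 arrays, adjusted p up to 0.117).

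In all, 2058 of 10435 genes passed in AB against sAB, 1256 higher and 802 lower, and 198 changed by at least 2-fold. After median centring 1086 were higher and 1075 lower, and after quantile normalization 1105 and 1058. The count for AB against sAB moved to 1229 without AB replicate 2 and 1139 without AB replicate 3. The Actb 3' minus 5' difference, a sign of RNA quality, was 1.02 to 1.13 on the AB arrays, below all sAB (1.20 to 1.26) and sDB3 arrays (1.20 to 1.25). That of Gapdh overlapped between these groups. With sDB3 in place of sAB, 2298 genes passed, 1809 higher and 489 lower in AB. This split turned to 738 and 1320 after median centring, which takes 0.15 from every difference where the median gene had 0.11, and to 918 and 726 after quantile normalization. The count for AB against sDB3 moved to 1231 without AB replicate 2, 1124 without AB replicate 3 and 1446 without sDB3 replicate 2. In the same direction in both comparisons, 873 genes passed, where independent lists would share 255. Simulated unchanged groups shared 0, but such groups gave 0 calls in any comparison, so this 0 does not show what the shared AB arrays add. Across genes, which are not independent replicates, the log2 differences correlated at 0.599, against 0.491 simulated. Their covariance was 0.0759, against 0.0146 simulated, and part of the excess of shared calls can come from the shared AB arrays. Against sDB3, Myh7 (2.91), Nppa (2.07), Nppb (1.43), Acta1 (1.70), Dio2 (3.38, dim in sDB3) and Cilp (2.83) passed in the same direction. So did Thbs4 (2.63), Ltbp2 (2.81), Tgfb2 (2.07), Ccn2 (1.74), Col8a1 (2.06), Postn (2.28) and Acot1 (-1.89), with adjusted p-values of at most 0.00664. Ret (-0.31, adjusted p = 0.519), Pcp4 (-0.11, adjusted p = 0.813), Retnla (-1.24, adjusted p = 0.236) and Col1a1 (1.19, adjusted p = 0.0958) did not, with Pcp4 dim in both groups.

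**Figure D2:**
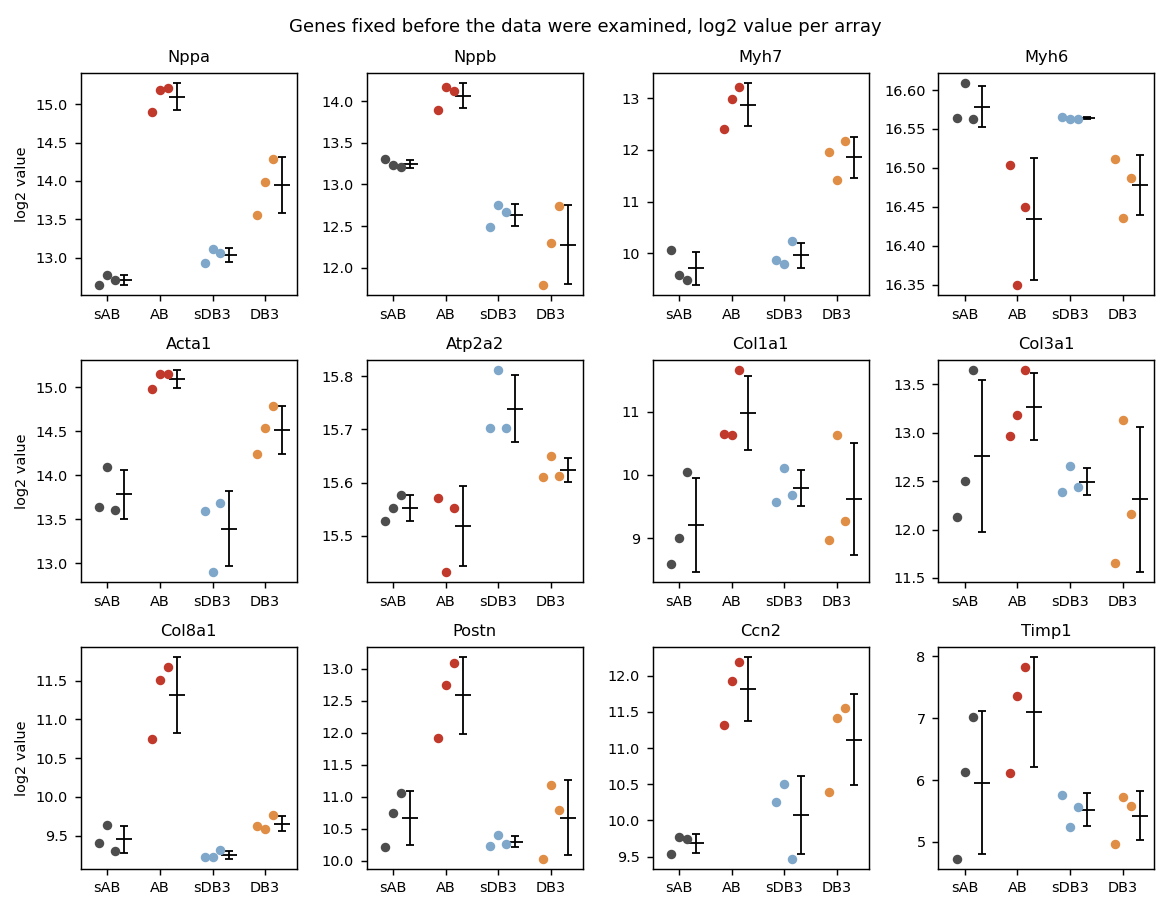
Log2 value (vertical axes) of 12 genes chosen before the data were examined, on each array by group (horizontal axes), where points are arrays and the black mark and bar give the mean and SD of 3. The 3 AB arrays lie above all other arrays for Nppa, Nppb, Myh7, Acta1, Col8a1 and Postn.

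By lists, 17 passed camera in AB against sDB3. Of 16 measured hypertrophy-associated genes, 12 rose and 0 fell (13 and 0 adjusted over the list alone). The hypertrophy-associated genes list had a median log2 difference of 1.38 and lay higher by camera (adjusted p = 2e-07, adjusted p = 0.0882 with an estimated correlation). Of 36 measured matrix glycoproteins and proteoglycans, 20 rose and 0 fell (26 and 0 adjusted over the list alone). The matrix glycoproteins and proteoglycans list had a median log2 difference of 0.92 and lay higher by camera (adjusted p = 6.45e-07, adjusted p = 0.332 with an estimated correlation). Of 31 measured fatty acid oxidation and transport genes, 0 rose and 17 fell (1 and 20 adjusted over the list alone). The fatty acid oxidation and transport list had a median log2 difference of -0.27 and lay lower by camera (adjusted p = 4.16e-14, adjusted p = 0.0882 with an estimated correlation). Of 13 measured potassium and sodium channels, 0 rose and 9 fell (0 and 10 adjusted over the list alone). The list had a median log2 difference of -0.54 and lay lower by camera (adjusted p = 1.47e-09). It alone passed with an estimated correlation (adjusted p = 0.0294), and held Kcnj3 (-1.05) and Scn4b (-0.88). Atrial (median -0.71, adjusted p = 0.0306), clock, glucocorticoid and blood lists lay lower too. Of the 13 lists that passed against sAB, 3 did not pass against sDB3. They were immediate early genes (camera adjusted p = 0.573), smooth muscle and pericyte markers (adjusted p = 0.535, median log2 difference 0.11, -0.04 after median centring) and macrophage markers (adjusted p = 0.791, median 0.26, where it was -0.30 against sAB).

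The comparison of DB3 with sDB3 asked what remained of the overload response, or followed its relief, 3 days after the band was removed. Parts of the hypertrophic programme were still higher. Myh7 was 3.71-fold higher in DB3 (log2 difference 1.89 ± 0.25, SE, n = 3 per group, limma adjusted p = 0.00929). Acta1 was 2.18-fold higher (1.13 ± 0.21, adjusted p = 0.0237) and Nppa 1.88-fold (0.91 ± 0.16, adjusted p = 0.0171). Nppb (-0.36), Col1a1 (-0.17), Col3a1 (-0.18), Col8a1 (0.40), Postn (0.37), Ccn2 (1.04), Timp1 (-0.10), Myh6 (-0.086) and Atp2a2 (-0.11) did not pass. Their adjusted p-values ran from 0.0898 for Ccn2 to 0.928 for Timp1. Among hypertrophy-associated genes, 4 of 16 measured members rose and 2 fell (4 and 2 adjusted over the list alone), with a median log2 difference of 0.062 and a camera adjusted p of 0.946. Other collagens (0 higher and 0 lower of 15, camera adjusted p = 0.274) and fibrillar collagens (camera adjusted p = 0.131) did not pass. Among matrix glycoproteins and proteoglycans, 4 of 36 measured members rose and 0 fell (7 and 0 adjusted over the list alone), and camera did not pass (adjusted p = 0.262). Thbs2, a thrombospondin, rose by 0.99. Calls lost without 1 array were those of Acta1 (without DB3 replicate 2 or DB3 replicate 3, adjusted p up to 0.054).

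Of the other genes with the largest rises in DB3, Apod, a lipid-binding secreted protein (1.76 ± 0.28, adjusted p = 0.0143), and Mthfd2, a mitochondrial enzyme of folate metabolism (1.52 ± 0.23, adjusted p = 0.0131), kept their call without any 1 array. The methyltransferase Inmt rose by 1.82, Ahnak2, a large scaffold protein, by 1.47, the oxidase Nox4 by 2.02 and the transcriptional regulator Eya1 by 1.56. Nox4 was dim in sDB3, and Eya1 in sDB3 and AB. Gnb3, a G protein subunit (1.75), the matricellular Ccn5 (1.62) and the predicted gene Gm19277 (1.52) were also higher. The falls that kept their call without any 1 array were Cideb, a lipid droplet protein (-1.02 ± 0.19, adjusted p = 0.0211), the cytokine signalling inhibitor Cish (-1.01 ± 0.14, adjusted p = 0.0102) and the coactivator Cited4 (-1.01 ± 0.11, adjusted p = 0.00423). Tfrc, the transferrin receptor, differed by -1.54 ± 0.34 (adjusted p = 0.0318). Slc12a5, a chloride transporter (-1.55), was dim in DB3 and AB. Kcna1, a potassium channel (-1.82), Chd6, a chromatin remodeller (-1.18), Armcx4 (-1.07), Aif1l (-0.99) and the transcription factor Mycn (-0.99) were lower too. A fit without 1 array ended the calls of Inmt (without sDB3 replicate 2, adjusted p up to 0.0503) and Ahnak2 (sDB3 replicate 2 or DB3 replicate 2, 0.0551). Others were Nox4 (4 arrays, 0.0957), Eya1 (4, 0.0682), Gnb3 (9, 0.102), Ccn5 (9, 0.104), Gm19277 (10, 0.118) and Tfrc (5, 0.0795). Calls lost without 1 array were those of Slc12a5 (without sDB3 replicate 2 or DB3 replicate 1, adjusted p up to 0.0665) and Kcna1 (10 arrays, 0.122). So were Chd6 (10, 0.102), Armcx4 (10, 0.108), Aif1l (11, 0.107) and Mycn (6, 0.0814).

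By camera the contraction, respiratory chain and fatty acid lists lay lower in DB3 than in sDB3 relative to the other genes, by small amounts, and the interferon response list lay higher. Of 55 measured respiratory chain and citrate cycle genes, 0 rose and 2 fell (0 and 1 adjusted over the list alone, 0 and 10 after median centring). The respiratory chain and citrate cycle list had a median log2 difference of -0.069 (-0.03 after quantile normalization) and lay lower by camera (adjusted p = 8.55e-12, adjusted p = 0.29 with an estimated correlation). Of 22 measured adult cardiac contraction and calcium handling genes, 0 rose and 0 fell (1 and 2 adjusted over the list alone, 0 and 5 after median centring). The adult cardiac contraction and calcium handling list had a median log2 difference of -0.086 and lay lower by camera (adjusted p = 5.08e-07, adjusted p = 0.29 with an estimated correlation). Of 31 measured fatty acid oxidation and transport genes, 0 rose and 0 fell (0 and 0 adjusted over the list alone, 0 and 3 after median centring). The fatty acid oxidation and transport list had a median log2 difference of -0.039 and lay lower by camera (adjusted p = 0.000511, adjusted p = 0.816 with an estimated correlation). Of 13 measured potassium and sodium channels, 0 rose and 1 fell (0 and 1 adjusted over the list alone). The potassium and sodium channels list had a median log2 difference of -0.16 and lay lower by camera (adjusted p = 0.00584, adjusted p = 0.29 with an estimated correlation). Of 8 measured atrial markers, 0 rose and 1 fell (0 and 1 adjusted over the list alone). The atrial markers list had a median log2 difference of -0.38 and lay lower by camera (adjusted p = 0.0442, adjusted p = 0.816 with an estimated correlation). Myl7, the atrial myosin light chain, ranged from 4.67 to 12.97 over the 12 arrays and did not pass (-2.88 ± 1.67, adjusted p = 0.306). Of 27 measured endoplasmic reticulum stress and protein folding genes, 0 rose and 4 fell (2 and 6 adjusted over the list alone). The endoplasmic reticulum stress and protein folding list had a median log2 difference of 0.026 (-0.025 after quantile normalization and -0.10 after median centring) and lay lower by camera, against the sign of its median, with a mean of 0.017 (adjusted p = 0.00745, adjusted p = 0.29 with an estimated correlation). Pdia6, a protein disulfide isomerase, differed by -0.50. Of 24 measured interferon response genes, 4 rose and 0 fell (7 and 0 adjusted over the list alone, 1 and 0 after median centring, 0 and 0 after quantile normalization). The interferon response list had a median log2 difference of 0.33 and lay higher by camera (adjusted p = 0.00745, adjusted p = 0.816 with an estimated correlation). Psmb9, an immunoproteasome subunit, rose by 0.97 and H2-K1, a class I histocompatibility antigen, by 0.69. Macrophage (0.807), endothelial (0.807) and fibroblast (0.946) markers did not pass camera, the brackets giving adjusted p-values. The sDB3 arrays themselves stood apart, with all 3 below the other 9 for 695 genes and above them for 112. AB against sDB3 moved the same way for the contraction (camera adjusted p = 0.00011), respiratory chain (adjusted p = 3.71e-14) and interferon (adjusted p = 0.0127, median 0.32) lists. With an estimated correlation none of these passed there (adjusted p = 0.241, 0.0882 and 0.491), and the contraction median of -0.088 became -0.0082 after quantile normalization. In DB3 against AB the contraction (adjusted p = 0.906, median 0.012) and interferon (adjusted p = 0.98, median 0.01) lists did not pass, and the respiratory chain list lay higher. When 1 array was left out, calls ended for Pdia6 (without sDB3 replicate 1 or sDB3 replicate 2, adjusted p up to 0.0626), Psmb9 (7 arrays, adjusted p up to 0.0976) and H2-K1 (11 arrays, adjusted p up to 0.136).

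In all, 664 genes passed in DB3 against sDB3, 560 higher and 104 lower, and 31 changed by at least 2-fold. This split follows the scaling of the arrays. After each array was centred on its median, which takes 0.13 from every difference where the median gene had 0.091, 127 genes were higher and 348 lower, and quantile normalization left 107 and 92. A limma fit of these 6 arrays alone passed 0 genes, with 2137 at an unadjusted p under 0.05. A fit without the sAB arrays passed 400. The count for DB3 against sDB3 moved to 434 without AB replicate 1, 375 without AB replicate 2, 394 without AB replicate 3, 230 without sDB3 replicate 1, 170 without sDB3 replicate 2, 206 without DB3 replicate 1, 235 without DB3 replicate 2 and 220 without DB3 replicate 3.

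Whether the difference from sham itself changed was tested as the DB3 minus sDB3 difference less the AB minus sAB difference. Many of the genes that passed in AB against sAB had a smaller difference from sham 3 days after debanding. Of the 2058 genes changed in AB against sAB, 473 had an effect that passed this test toward sham and 0 one that passed it further away from sham. The median log2 difference of the genes higher in AB was 0.50 at 4 weeks and 0.18 at 3 days. That of the genes lower in AB was -0.40 and -0.013. How near 0 each side lay at 3 days depends on the scaling. The 3-day medians of these genes were 0.049 and -0.14 after median centring and 0.10 and -0.085 after quantile normalization. Selection for a large change at 4 weeks alone pulls the later value toward 0, and the sAB arrays enter 1 side of this test. Of the 473 genes, 188 also passed toward sham in DB3 against AB. This comparison uses no sAB array but shares the AB and DB3 arrays, so that the choice of the genes by their AB values favours such an overlap. Over all genes the log2 differences of these tests correlated at 0.594, below the 0.706 of simulated unchanged groups, with a covariance of 0.0718 against 0.0301 simulated. At 3 days 1473 of the 2058 genes (71.6%) differed from sham in the same direction, against 60.6% of all tested genes. Of the genes higher in AB 83.1% did, against 78.6% of tested genes with a rise of any size in AB. Of the genes lower in AB 53.5% did, against 41% of tested genes with a fall. After median centring these shares were 60% (against 52.5%) and 80.5% (against 68.4%). Among the 1473 genes, 188 passed in that direction, where independent lists would share 75.4, and 18 of the 2058 passed in the opposite one. Of the 188, 157 were higher. Median centring left 127 and quantile normalization 107 genes higher in DB3 against sDB3, so not all 157 would stay. The 188 were not recounted. The tests share each gene's spread, so 75.4 is no exact chance level.

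**Figure D3:**
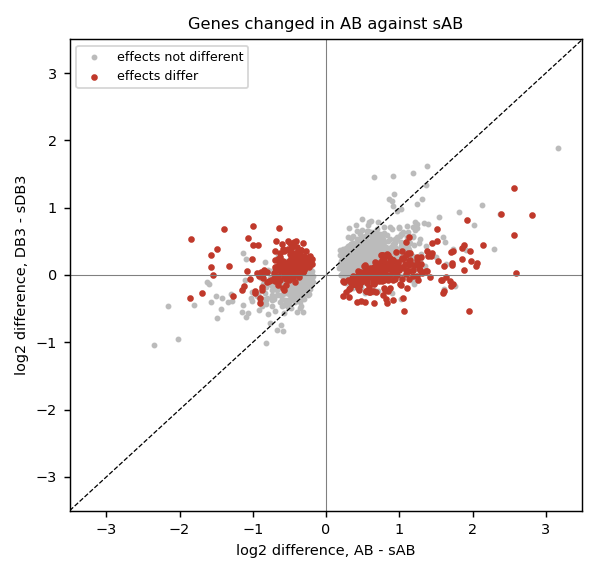
Log2 difference of AB minus sAB (horizontal axis) against that of DB3 minus sDB3 (vertical axis) for the 2058 genes that passed in AB against sAB, where each point is a gene and the dashed line marks equal effects. The 473 genes in red are those whose effects differ between the times, all on the sham side of the dashed line.

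The largest drops that passed were those of Lman1l, dim outside AB (-2.55 ± 0.28, adjusted p = 0.002), Nmrk2, a kinase of NAD synthesis (-2.48 ± 0.51, adjusted p = 0.0251), Thbs4 (-1.96) and Cilp (-1.92). Next were the integrin Itga5 (-1.91), the translation regulator Eif4ebp2 (-1.88), the adaptor subunit Ap2a1 (-1.87) and Col15a1 (-1.87 ± 0.22, adjusted p = 0.00294). The predicted gene Gm30873 (-1.86) and Adamtsl2, a matrix protein (-1.85), followed. Smaller drops among genes chosen beforehand or by list were those of Tgfb2 (-1.70 ± 0.29, adjusted p = 0.0124), Nppa (-1.48 ± 0.22, adjusted p = 0.0075), Col8a1 (-1.46) and Nppb (-1.19). Myh7 (-1.27 ± 0.35, adjusted p = 0.0611), Postn (-1.53), Col1a1 (-1.93), Ccn2 (-1.09), Timp1 (-1.24), Col3a1 (-0.69), Acta1 (-0.19), Atp2a2 (-0.081) and Myh6 (0.058) did not pass. Of the 48 genes named for the difference of effects here or below, all 3 sAB arrays lay below the other 9 for Ap2a1, Calr, Col15a1, Eif4ebp2, Hk1, Itga5, Jph2, Nppa, Nr1d1 and Pfkl, and above them for Pcp4. Col15a1 rose by 0.97 in AB over sDB3 where it rose by 1.70 over sAB, and sDB3 lay 0.73 above sAB. Effects that moved upward included those of Tbc1d10c (1.87 ± 0.30, adjusted p = 0.0114), Pcp4, dim outside sAB (2.37), Scara5, a ferritin receptor (1.88), and the clock gene Per1 (2.01). Inmt (1.83), Eya1, dim in AB and sDB3 (1.80), the transcription factors Irx1 (2.07) and Bcl11b (2.18), the polymerase Poln (1.73) and Gm19277 (2.44) also moved upward. Calls lost without 1 array were those of Nmrk2 (4 arrays, adjusted p up to 0.0657), Thbs4 (9, 0.0749), Cilp (11, 0.0954) and Col8a1 (AB replicate 2, 0.0521). Others were Nppb (9, 0.0807), Scara5 (5, 0.0542), Per1 (10, 0.101) and Inmt (10, 0.087). The last were Eya1 (9, 0.0953), Irx1 (8, 0.0864), Bcl11b (11, 0.112), Poln (8, 0.0965) and Gm19277 (8, 0.0678).

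By camera with the preset correlation, the effect in 8 lists lay lower at 3 days, those of hypertrophy, collagens, matrix glycoproteins, glycolysis, contraction and TGF-beta signalling among them, and in the fatty acid list higher. Several had few or 0 members passing, and none passed with an estimated correlation. Here members that rose or fell are those with a higher or lower difference from sham at 3 days. Of 16 measured hypertrophy-associated genes, 0 rose and 9 fell (0 and 12 adjusted over the list alone). The hypertrophy-associated genes list had a median log2 difference of -1.22 and lay lower by camera (adjusted p = 2.86e-13, adjusted p = 0.0707 with an estimated correlation). Uck2, a uridine kinase, changed by -1.65. Of 15 measured other collagens, 0 rose and 5 fell (0 and 9 adjusted over the list alone). The other collagens list had a median log2 difference of -0.79 and lay lower by camera (adjusted p = 3.43e-10, adjusted p = 0.382 with an estimated correlation). Of 36 measured matrix glycoproteins and proteoglycans, 1 rose and 5 fell (1 and 7 adjusted over the list alone). The matrix glycoproteins and proteoglycans list had a median log2 difference of -0.40 and lay lower by camera (adjusted p = 0.000159, adjusted p = 0.602 with an estimated correlation). Of 18 measured collagen processing and crosslinking genes, 0 rose and 1 fell (0 and 1 adjusted over the list alone). The collagen processing and crosslinking list had a median log2 difference of -0.25 and lay lower by camera (adjusted p = 0.000573, adjusted p = 0.602 with an estimated correlation). Of 6 measured fibrillar collagens, 0 rose and 1 fell (0 and 2 adjusted over the list alone). The fibrillar collagens list had a median log2 difference of -0.84 and lay lower by camera (adjusted p = 0.00563, adjusted p = 0.602 with an estimated correlation). Of 22 measured adult cardiac contraction and calcium handling genes, 0 rose and 3 fell (1 and 5 adjusted over the list alone). The adult cardiac contraction and calcium handling list had a median log2 difference of -0.06 (-0.013 after quantile normalization) and lay lower by camera (adjusted p = 0.0101, adjusted p = 0.602 with an estimated correlation). Of 20 measured glycolysis and glucose uptake genes, 1 rose and 4 fell (1 and 5 adjusted over the list alone). The glycolysis and glucose uptake list had a median log2 difference of -0.093 and lay lower by camera (adjusted p = 0.0169, adjusted p = 0.602 with an estimated correlation). Pfkl, liver phosphofructokinase, changed by -0.86. Of 33 measured TGF-beta and BMP signalling genes, 1 rose and 4 fell (3 and 6 adjusted over the list alone). The TGF-beta and BMP signalling list had a median log2 difference of -0.18 and lay lower by camera (adjusted p = 0.0204, adjusted p = 0.602 with an estimated correlation). Of 31 measured fatty acid oxidation and transport genes, 0 rose and 0 fell (5 and 0 adjusted over the list alone). The fatty acid oxidation and transport list had a median log2 difference of 0.16 (0.066 after median centring) and lay higher by camera (adjusted p = 0.0468, adjusted p = 0.828 with an estimated correlation). In all, 630 genes passed, 360 with a higher and 270 with a lower difference from sham at 3 days. After median centring 153 were higher and 430 lower, and after quantile normalization 229 and 344. The count for the difference of effects moved to 353 without sAB replicate 1, 410 without sAB replicate 2, 326 without sAB replicate 3, 178 without AB replicate 2, 152 without AB replicate 3, 275 without sDB3 replicate 1, 344 without sDB3 replicate 2, 396 without DB3 replicate 1, 354 without DB3 replicate 2 and 363 without DB3 replicate 3.

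DB3 was set directly against AB to ask what differs 3 days after the band is removed, without the sAB arrays but with the second operation and the 3 days included. Natriuretic peptide genes, Col8a1 and Postn were lower in DB3. Nppb differed by -1.80 ± 0.19 (log2, SE, n = 3 per group, limma adjusted p = 0.000826), Nppa by -1.16 ± 0.16 (adjusted p = 0.0026), Col8a1 by -1.66 ± 0.20 (adjusted p = 0.00144) and Postn by -1.91 ± 0.34 (adjusted p = 0.00788). Myh7 differed by -1.02 ± 0.25 (adjusted p = 0.031). Acta1 (-0.58), Col1a1 (-1.36), Col3a1 (-0.95), Ccn2 (-0.70), Timp1 (-1.68), Myh6 (0.043) and Atp2a2 (0.11) did not pass. The largest falls were Dio2 (-2.99) and Lman1l (-2.56), both dim in DB3, Nmrk2 (-2.39) and the clock genes Npas2 (-2.35) and Arntl (-2.35). The largest rises were the clock genes Per1 (3.39), Ciart (3.32), Dbp (2.87) and Per2 (2.79), with Ciart and Per2 dim in AB, and Inmt (2.56). A fit without 1 array ended the calls of Myh7 (4 arrays, adjusted p up to 0.124), Arntl (5, 0.107) and Ciart (6, 0.0845). So did that of Per2 (AB replicate 2 or 3 or DB3 replicate 3, 0.0685).

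By camera the hypertrophy, collagen and matrix glycoprotein lists lay lower in DB3 than in AB, and fatty acid and channel lists higher. Of 16 measured hypertrophy-associated genes, 0 rose and 12 fell (0 and 13 adjusted over the list alone). The hypertrophy-associated genes list had a median log2 difference of -0.86 and lay lower by camera (adjusted p = 7.5e-12, adjusted p = 0.0871 with an estimated correlation). Rcan1, a calcineurin-regulated gene, differed by -2.04 and Meox1 by -1.99. Of 15 measured other collagens, 0 rose and 10 fell (0 and 12 adjusted over the list alone). The other collagens list had a median log2 difference of -0.97 and lay lower by camera (adjusted p = 3.07e-11, adjusted p = 0.123 with an estimated correlation). Of 6 measured fibrillar collagens, 0 rose and 2 fell (0 and 6 adjusted over the list alone). The fibrillar collagens list had a median log2 difference of -1.15 and lay lower by camera (adjusted p = 0.000407, adjusted p = 0.306 with an estimated correlation). Col4a3, dim in DB3, differed by -1.60 and Col5a3 by -1.49. Of 36 measured matrix glycoproteins and proteoglycans, 1 rose and 13 fell (2 and 18 adjusted over the list alone). The matrix glycoproteins and proteoglycans list had a median log2 difference of -0.62 and lay lower by camera (adjusted p = 2.98e-06, adjusted p = 0.41 with an estimated correlation). Thbs4 differed by -2.03 and Cilp by -1.93. Of 18 measured collagen processing and crosslinking genes, 0 rose and 6 fell (0 and 8 adjusted over the list alone). The collagen processing and crosslinking list had a median log2 difference of -0.37 and lay lower by camera (adjusted p = 4.85e-05, adjusted p = 0.306 with an estimated correlation). Of 31 measured fatty acid oxidation and transport genes, 6 rose and 0 fell (9 and 0 adjusted over the list alone). The fatty acid oxidation and transport list had a median log2 difference of 0.18 and lay higher by camera (adjusted p = 9.28e-08, adjusted p = 0.25 with an estimated correlation). Acot1 differed by 1.44. Of 13 measured potassium and sodium channels, 4 rose and 0 fell (7 and 0 adjusted over the list alone). The potassium and sodium channels list had a median log2 difference of 0.39 and lay higher by camera (adjusted p = 4.85e-05, adjusted p = 0.0871 with an estimated correlation). Kcnv2, dim in AB, differed by 0.75. Of 55 measured respiratory chain and citrate cycle genes, 3 rose and 0 fell (0 and 0 adjusted over the list alone). The respiratory chain and citrate cycle list had a median log2 difference of 0.034 and lay higher by camera (adjusted p = 0.0297, adjusted p = 0.698 with an estimated correlation). Of 20 measured endothelial markers, 0 rose and 3 fell (0 and 5 adjusted over the list alone). The endothelial markers list had a median log2 difference of -0.17 and lay lower by camera (adjusted p = 0.0211, adjusted p = 0.123 with an estimated correlation). Of 12 measured cell cycle genes, 0 rose and 1 fell (0 and 2 adjusted over the list alone). The cell cycle list had a median log2 difference of -0.36 and lay lower by camera (adjusted p = 0.0285, adjusted p = 0.698 with an estimated correlation). Over all genes 956 passed, 422 higher and 534 lower. Without the sAB arrays in the fit the count was 734. The count for DB3 against AB moved to 407 without AB replicate 2, 365 without AB replicate 3, 608 without DB3 replicate 1 and 634 without DB3 replicate 3.

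**Figure D4:**
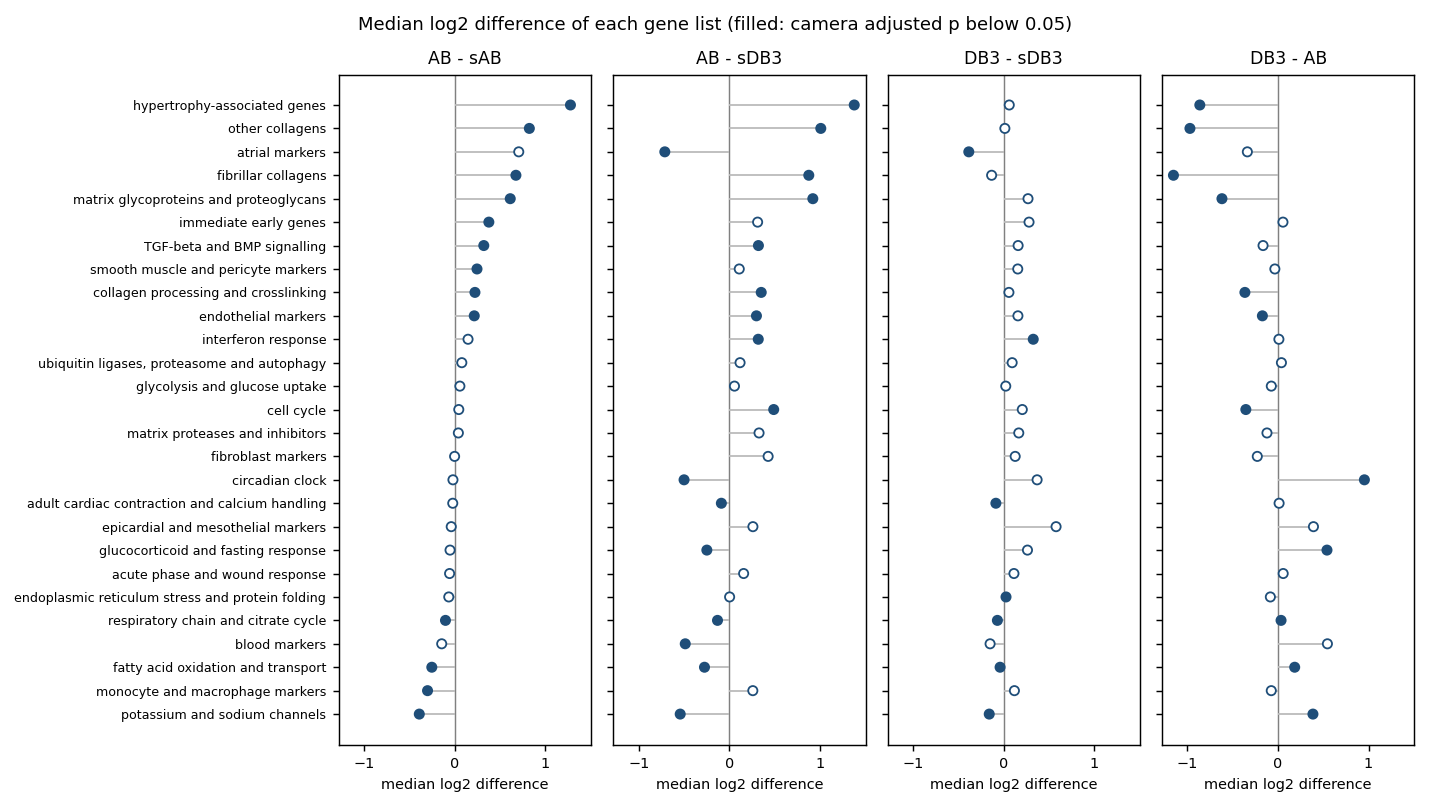
Median log2 difference (horizontal axes) of the measured members of each of 27 gene lists (vertical axis) in 4 comparisons, where filled points mark a camera adjusted p below 0.05 with the preset correlation. The hypertrophy-associated genes have medians of 1.28, 1.38, 0.062 and -0.86 from left to right.

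The shams differed from each other as well. sDB3 against sAB asked what the second sham procedure and the 3 days change, and here the sAB batch cannot be told apart from them. Clock genes were among the largest differences. Dbp differed by 2.35 ± 0.53 (log2, SE, n = 3 per group, limma adjusted p = 0.0157) and Nr1d1 by 2.17 ± 0.22 (adjusted p = 0.000347), with AB 1.74 above sAB. Arntl differed by -2.07 ± 0.58 (adjusted p = 0.0341) and Npas2 by -1.85 ± 0.37 (adjusted p = 0.00996). Of 18 measured circadian clock genes, 6 rose and 4 fell (10 and 4 adjusted over the list alone). The circadian clock list had a median log2 difference of 0.75 and lay higher by camera (adjusted p = 0.00274, adjusted p = 0.366 with an estimated correlation). In DB3 against AB the clock genes moved alike. Of 18 measured circadian clock genes, 11 rose and 3 fell (11 and 5 adjusted over the list alone). The circadian clock list had a median log2 difference of 0.95 and lay higher by camera (adjusted p = 0.000367, adjusted p = 0.0871 with an estimated correlation). In DB3 against sDB3 the list did not pass (camera adjusted p = 0.856). A single array departed from this pattern. sDB3 replicate 3 had Arntl at 7.31 and Per2 at 2.71, near the AB means of 7.63 and 2.60 (Per2 was dim in sAB and AB). When 1 array was left out, calls ended for Dbp (without sAB replicate 2 or sDB3 replicate 1 or sDB3 replicate 2, adjusted p up to 0.0597) and Arntl (5 arrays, adjusted p up to 0.112).

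**Figure D5:**
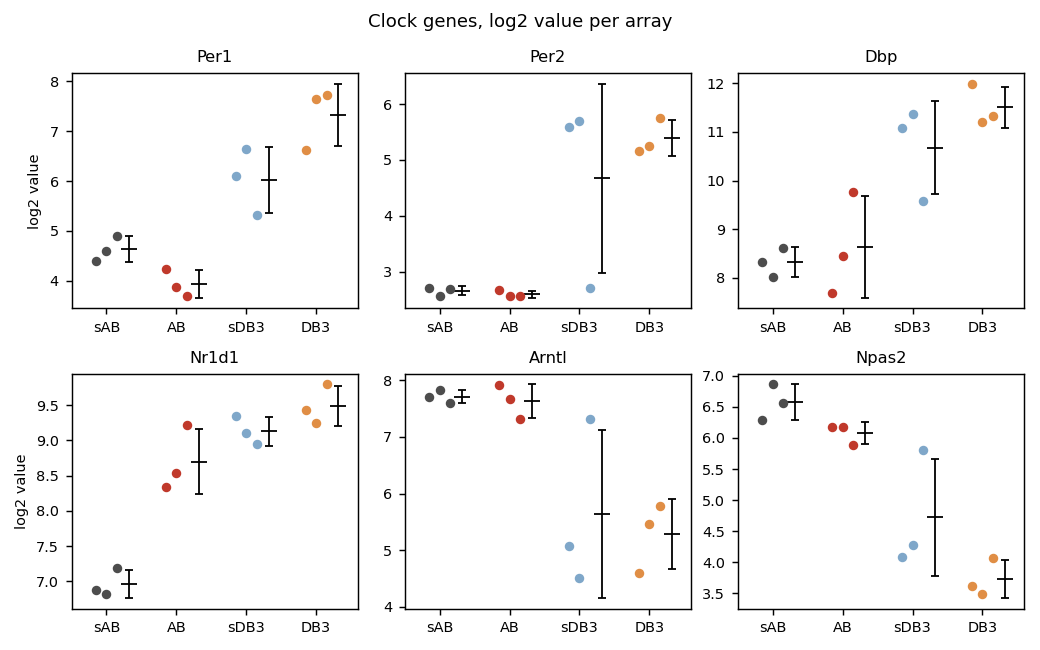
Log2 value (vertical axes) of 6 clock genes on each array by group (horizontal axes), where points are arrays and the black mark and bar give the mean and SD of 3. The DB3 arrays lie below all 4-week arrays for Arntl and Npas2 and above them for Per1, Per2 and Dbp, and sDB3 replicate 3 lies near the 4-week arrays for Arntl and Per2.

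By camera the glucocorticoid and fasting response list lay higher in sDB3, and the cell cycle and macrophage lists lower. Of 17 measured glucocorticoid and fasting response genes, 6 rose and 0 fell (7 and 0 adjusted over the list alone). The glucocorticoid and fasting response list had a median log2 difference of 0.47 and lay higher by camera (adjusted p = 0.000354, adjusted p = 0.558 with an estimated correlation). Mt2, a metallothionein, rose by 1.06. In DB3 against AB this list moved the same way. Of 17 measured glucocorticoid and fasting response genes, 5 rose and 0 fell (8 and 1 adjusted over the list alone). The glucocorticoid and fasting response list had a median log2 difference of 0.54 and lay higher by camera (adjusted p = 4.85e-05, adjusted p = 0.25 with an estimated correlation). Of 12 measured cell cycle genes, 0 rose and 5 fell (0 and 8 adjusted over the list alone). The cell cycle list had a median log2 difference of -0.45 and lay lower by camera (adjusted p = 0.00866, adjusted p = 0.746 with an estimated correlation). Of 26 measured monocyte and macrophage markers, 0 rose and 5 fell (0 and 5 adjusted over the list alone, 0 and 1 after median centring, 0 and 3 after quantile normalization). The monocyte and macrophage markers list had a median log2 difference of -0.49 and lay lower by camera (adjusted p = 0.018, adjusted p = 0.846 with an estimated correlation). Mki67, a marker of dividing cells that was dim in sDB3, differed by -2.12. Of 22 measured adult cardiac contraction and calcium handling genes, 2 rose and 0 fell (5 and 0 adjusted over the list alone, 6 and 0 after median centring). The adult cardiac contraction and calcium handling list had a median log2 difference of 0.078 (0.031 after quantile normalization) and lay higher by camera (adjusted p = 0.000985, adjusted p = 0.682 with an estimated correlation). Of 13 measured potassium and sodium channels, 3 rose and 0 fell (3 and 0 adjusted over the list alone). The potassium and sodium channels list had a median log2 difference of 0.23 and lay higher by camera (adjusted p = 0.00532, adjusted p = 0.42 with an estimated correlation). Of 20 measured glycolysis and glucose uptake genes, 4 rose and 1 fell (5 and 1 adjusted over the list alone). The glycolysis and glucose uptake list had a median log2 difference of 0.07 and lay higher by camera (adjusted p = 0.0122, adjusted p = 0.682 with an estimated correlation). Of 8 measured atrial markers, 1 rose and 0 fell (1 and 0 adjusted over the list alone). The atrial markers list had a median log2 difference of 0.82 and lay higher by camera (adjusted p = 0.0136, adjusted p = 0.682 with an estimated correlation). Of 55 measured respiratory chain and citrate cycle genes, 3 rose and 1 fell (2 and 0 adjusted over the list alone, 15 and 0 after median centring). The respiratory chain and citrate cycle list had a median log2 difference of 0.0025 (-0.03 after quantile normalization) and lay higher by camera (adjusted p = 0.0149, adjusted p = 0.746 with an estimated correlation). Calls lost without 1 array were those of Mki67 (4 arrays, adjusted p up to 0.0822).

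Other large rises, in Eif4ebp2 (2.03), Bcat2 of amino acid catabolism (2.03) and the receptor Lrp5 (1.93), came with low values on the sAB arrays. Large falls were in the matrix protein Spon2 (-2.22), dim in sDB3 and DB3, and the transcription factor Irx2 (-1.95). Of the 12 genes chosen before the data were examined, Nppb passed (-0.61 ± 0.19, adjusted p = 0.0489). The other 11 did not, with differences from -0.44 for Timp1 to 0.58 for Col1a1. In all, 1861 genes passed in sDB3 against sAB, 573 higher and 1288 lower. This split turned to 1058 higher and 481 lower after median centring, which adds 0.11 to every difference where the median gene had -0.094, and to 712 and 735 after quantile normalization. The count for sDB3 against sAB moved to 1121 without sAB replicate 2, 1131 without sAB replicate 3, 1178 without sDB3 replicate 1 and 967 without sDB3 replicate 2. With AB against sAB it shared 672 genes in the same direction, where independent lists would share 168 and simulated unchanged groups with the same sAB arrays shared 0. The log2 differences correlated across genes at 0.451, below the 0.501 simulated. Their covariance was 0.0514, against 0.015 simulated, and part of the excess of shared calls can come from the shared arrays. Over the 4 groups together the F test passed 3881 of 10435 genes. A fit without 1 array ended the calls of Irx2 (9 arrays, adjusted p up to 0.132) and Nppb (10 arrays, adjusted p up to 0.129).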

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

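The tests on BioC, on genes shared between AB against sAB and AB against sDB3, on clock genes and with Myl7 as a covariate were chosen after those results were seen. BioC, which no comparison of the report uses as a measurement, was higher on the sAB arrays than on all others, with a gap of 1.55 log2 units. An overall signal or normalization difference would move the other spiked controls too, but their median difference was -0.21 where BioC moved by 1.96. Against RNA degradation, the sAB Actb 3' minus 5' difference was 0.0445 above the other arrays' mean (SD 0.10). RNA quality of the AB arrays, with the lowest mean difference, was not tested. A separate hybridisation batch of the sAB arrays is therefore a candidate explanation for the gap, and no biological explanation applies to a control added to the mix. As the sole cause of the changes in AB against sAB it is argued against for 873 genes as a set. They passed the same way in AB against sDB3, without sAB arrays. Independent lists would share 255, which the shared AB arrays raise, but covariance was 0.0759 against 0.0146 simulated. Of the 873, 627 were higher in AB, a side that depends on the scaling, and none were recounted after rescaling. For the other 1185 genes batch and banding cannot be told apart, because every comparison with the sham of the AB group uses the sAB arrays. Of them 614 also passed in sDB3 against sAB in the same direction and 571 did not. The choice of genes and the shared sAB arrays favour that direction, so this decides nothing.

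Clock genes separated the 3-day from the 4-week mice. Of 15 measured clock genes in opposed phases, 15 had the sign that 1 shift of phase would give in both DB3 against AB and sDB3 against sAB, where 13 and 9 of them passed. Of the 9, Nr1d1 was also higher in AB than sAB. Tissue collected at another time of day fits these signs. The phase score, the mean of both arms against the 4-week arrays, was 0.37 in sDB3 replicate 3, against 1.56 and 1.77 in the other sDB3 arrays and at most 0.31 in the 4-week arrays. An effect of the second operation cannot be told apart from time of day, because 0 of 6 arrays of 3-day mice lay within the 4-week range and the collection times are not given here.

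Nppa is abundant in atrial muscle, and the atrial light chain Myl7 varied from 4.67 to 12.97 over the arrays, so that atrial tissue in some samples could raise Nppa. With Myl7 as a covariate the Nppa difference was 2.50 in AB against sAB (95% interval 2.13 to 2.86, adjusted p = 4.15e-05), where it was 2.39 without. In DB3 against sDB3 it went from 0.91 to 0.79 (0.41 to 1.17), and its adjusted p from 0.0171 to 0.0517. Atrial tissue as the whole cause is argued against in AB, since the difference stayed above 50% of its size and its interval excluded 0. Mean Myl7 was lower in DB3 than sDB3, so atrial tissue would lower Nppa. The response of the ventricle to load, the biological explanation of the design, stays open and carries the confounding of the sAB arrays in the 4-week comparison.

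Other splits of the arrays were counted for each number of genes. Of 6 arrays there are 10 splits into 3 and 3, too few for a share under 0.05, and 1 split in each comparison, the real one, gave as many genes. There were 2058 in AB against sAB with 0 as the highest other and 664 in DB3 against sDB3 with 2. There were 1861 in sDB3 against sAB with 2, 956 in DB3 against AB with 0 and 2298 in AB against sDB3 with 0. For the F test 1 of 100 drawn splits, the real one with 3881 genes, gave as many, with 224 as the highest other, and a chance split is excluded. For the difference of effects 4 of 100 splits drawn within the times gave at least 630 genes, the real one included. Most of the 100 also mix sAB with AB and so stand for no effect at all, where the question is whether the effects are equal. With sAB and AB kept whole there are 20 splits of the 3-day arrays, too few for a share under 0.05, and 5 of them gave as many. The highest other, 2308, swaps the labels at 1 time and so adds the effects in place of subtracting them. The 18 that mix sDB3 with DB3 gave 181 to 741 genes, so that such counts follow the sAB to AB difference and the share does not test equal effects.

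The test of the difference itself was passed by 630 genes, those below among them, and 9 lists. The lists passed camera with the preset correlation, 0 with an estimated one (lowest adjusted p = 0.0707) and 2 with fry. The median log2 differences of the lists were -1.22 for hypertrophy-associated genes, -0.84 for fibrillar collagens, -0.79 for other collagens, -0.40 for matrix glycoproteins and proteoglycans, -0.25 for collagen processing and crosslinking, -0.18 for TGF-beta and BMP signalling, -0.093 for glycolysis and glucose uptake, -0.06 for adult cardiac contraction and calcium handling and 0.16 for fatty acid oxidation and transport. Among hypertrophy-associated genes the log2 differences were -1.48 for Nppa, -1.19 for Nppb, -1.65 for Uck2 and -1.62 for Meox1. Collagen genes had -1.46 for Col8a1, -1.87 for Col15a1, -1.31 for Col4a3 and -1.08 for Col5a3. Other matrix genes had -1.96 for Thbs4, -1.92 for Cilp, -0.57 for P3h2 and -1.85 for Adamtsl2. For growth factor signalling genes and a ferritin receptor they were -1.70 for Tgfb2, -0.87 for Fstl3, 0.93 for Id1 and 1.88 for Scara5. Muscle and channel genes had -0.91 for Slc8a1, -0.46 for Jph2, -0.45 for Mybpc3, -1.07 for Myl1 and 0.75 for Kcnv2. Metabolic genes had -0.86 for Pfkl, -0.76 for Pfkp, -0.65 for Hk1, 0.91 for Pfkfb3 and -2.48 for Nmrk2. For stress and autophagy genes they were -0.86 for Calr, 0.60 for Foxo3 and 0.59 for Map1lc3b. For clock and early response genes they were -1.45 for Egr2, 2.01 for Per1 and -1.38 for Nr1d1. Vessel and macrophage markers had -0.98 for Cx3cr1, -0.81 for Cspg4 and -0.63 for Mcam. The remaining genes that dropped had -2.55 for Lman1l, -1.86 for Gm30873, -1.91 for Itga5, -1.88 for Eif4ebp2 and -1.87 for Ap2a1. Those that moved upward had 2.44 for Gm19277, 2.37 for Pcp4, 2.18 for Bcl11b, 2.07 for Irx1 and 1.87 for Tbc1d10c, and 1.83 for Inmt, 1.80 for Eya1 and 1.73 for Poln. Genes named elsewhere in the text passed too, with -1.77 for Lrp5, -1.66 for Bcat2, -1.29 for Rcan1, -1.28 for Cnksr1 and -0.81 for Tgfb1, with -0.79 for Alas1, -0.67 for Cited4 and -0.60 for Atf5 and with 1.52 for Aqp4, 1.43 for Fbp2 and 1.03 for Thbs2. Of these 11, all 3 sAB arrays lay below the other 9 for Atf5, Bcat2, Cnksr1, Lrp5 and Tgfb1 and above them for Aqp4 and Fbp2. Egr2, Col4a3 and Lman1l were dim outside AB, Pcp4 and Aqp4 outside sAB, Kcnv2 in AB and Eya1 in AB and sDB3. Leaving out 1 array cannot test an offset of all 3 sAB arrays. Of 12 fits that each left out 1 array, 0 ended the call of Adamtsl2, Ap2a1, Aqp4, Bcat2, Calr, Col15a1, Egr2, Eif4ebp2, Gm30873, Itga5, Kcnv2, Lman1l, Lrp5, Nppa, Pcp4, Pfkl, Tbc1d10c, Tgfb2 and Uck2. The number of fits that ended it was 1 for Alas1, Col4a3, Col8a1 and Map1lc3b, 2 for Fbp2, Jph2 and Mcam, 4 for Nmrk2 and Tgfb1, 5 for Cnksr1 and Scara5 and 6 for Myl1. It was 7 for Atf5, Fstl3, Hk1 and Thbs2, 8 for Cited4, Cspg4, Gm19277, Irx1, Mybpc3, Nr1d1 and Poln, 9 for Col5a3, Cx3cr1, Eya1, Id1, Nppb, Rcan1 and Thbs4, 10 for Foxo3, Inmt, Meox1, Per1, Pfkfb3, Pfkp and Slc8a1 and 11 for Bcl11b, Cilp and P3h2, with adjusted p-values up to 0.112.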

How the results depend on the processing

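The alternatives without sAB arrays and with sDB3 as the control were chosen after seeing the data. Counts of genes moved by over 1.5 times as follows, and the cause was not tested except where the setting tests more genes, uses fewer arrays or moves the threshold. Without a dim filter, which adds dim genes to the adjustment, they were 323 in DB3 against sDB3 and 338 in the difference of effects. With quantile normalization there were 199 in DB3 against sDB3. Fits of only the groups compared, with fewer arrays to estimate the spread, gave 0 in DB3 against sDB3, 571 in sDB3 against sAB and 629 in DB3 against AB. In limma the fit with 0 genes had 2137 at an unadjusted p under 0.05. The unmoderated analysis of variance gave 427 in DB3 against sDB3, array weights 400 in DB3 against sDB3 and the fit without the sAB arrays 400 in DB3 against sDB3. A 1.5-fold minimum left 671 in AB against sAB, 168 in DB3 against sDB3, 381 in the difference of effects, 459 in sDB3 against sAB, 380 in DB3 against AB, 743 in AB against sDB3 and 1367 in the F test, and an adjusted p of 0.1 gave 1403 in DB3 against sDB3, 1242 in the difference of effects, 2950 in sDB3 against sAB and 1571 in DB3 against AB. Leaving out 1 array gave 1139 to 2119 in AB against sAB, 170 to 535 in DB3 against sDB3, 152 to 567 in the difference of effects, 967 to 1945 in sDB3 against sAB, 365 to 1031 in DB3 against AB and 1124 to 2354 in AB against sDB3. The F test moved less (2727 to 3746). The log2 above 6 filter, mean of probe sets, every probe set and trended moderation kept counts within 1.5 times. After median centring, which takes 0.15 from every difference in AB against sDB3 and moves the median gene from 0.11 to -0.042, the higher share went from 78.7% to 35.9%. After quantile normalization it was 55.8%, so the direction of small changes in that comparison depends on the scaling. The share of genes changed at 4 weeks that kept their direction, 71.6%, was 76.2% at an adjusted p of 0.01, 68.9% to 75.6% without 1 array and 87.2% with sDB3 as the control at both times, which shares those arrays between both sides. Numbers of lists past the threshold were 0 in AB against sAB, 0 in DB3 against sDB3, 0 in the difference of effects, 0 in sDB3 against sAB, 0 in DB3 against AB and 1 in AB against sDB3 with an estimated correlation (2, 4, 3, 2 and 5 at an unadjusted p under 0.05 in the comparisons with 0). They were 4 in DB3 against sDB3, 2 in the difference of effects and 0 in sDB3 against sAB with fry (6 at an unadjusted p under 0.05 in sDB3 against sAB). Of 361 calls on named genes, 167 held under every alternative in which the gene was tested, 171 were lost without 1 or more arrays and 0 turned direction. Myh6 in sDB3 against sAB, not called as reported, was 0.31 with the mean of its probe sets (adjusted p = 0.0494).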

Other observations

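The genes of this part were chosen after their values were seen, and no explanation is offered for them. They are single genes, and no list of them was fixed or tested. Tfrc, the transferrin receptor through which cells take up iron, was at 10.66 ± 0.25 (log2, SD, n = 3) in DB3 against 12.26 ± 0.34 in sAB, 12.35 ± 0.11 in AB and 12.20 ± 0.84 in sDB3. Its call in DB3 against sDB3 (adjusted p = 0.0318) ended in 5 of 12 fits without 1 array (adjusted p up to 0.0795). Alas1, the rate-limiting enzyme of heme synthesis, differed by -0.96 ± 0.11 (SE) in DB3 against sDB3 (adjusted p = 0.00465) and by -0.86 ± 0.11 in DB3 against AB (adjusted p = 0.00202), and by -0.17 in AB against sAB without passing (adjusted p = 0.303). Hmox1, which breaks heme down, was higher in DB3 than sDB3 (0.96 ± 0.17, adjusted p = 0.0172) but not than AB (0.16 ± 0.17, adjusted p = 0.618). The iron exporter Slc40a1 (0.11 ± 0.14, adjusted p = 0.653) and the ferritin heavy chain Fth1 (-0.05 ± 0.06, adjusted p = 0.633) did not pass in DB3 against sDB3. Ferrochelatase, Fech, was higher in DB3 than in AB (0.60 ± 0.12, adjusted p = 0.0141), a call that ended without AB replicate 2 or AB replicate 3 (adjusted p up to 0.0635).

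The folate enzyme Mthfd2 was higher in AB than sAB by 1.19 ± 0.23 (adjusted p = 0.00578) and than sDB3 by 1.72 ± 0.23 (adjusted p = 0.00119), and in DB3 against AB it differed by -0.20 ± 0.23 (adjusted p = 0.649). Asns, asparagine synthetase, was higher in AB than sAB (1.36 ± 0.18, adjusted p = 0.00071) and lower in DB3 than AB (-0.91 ± 0.18, adjusted p = 0.0119). The amino acid transporter Slc7a5 (2.02 ± 0.26, dim in sAB), the transcription factor Atf5 (1.10 ± 0.093) and Aldh18a1 of proline synthesis (0.70 ± 0.13) were also higher in AB than sAB, with adjusted p-values of 0.000659, 6.86e-05 and 0.00511. Each passed against sDB3 too (1.11, 0.55 and 0.49). Against sDB3 the call of Slc7a5 ended without AB replicate 2 (adjusted p up to 0.0547) and that of Aldh18a1 in 4 of 12 fits without 1 array (adjusted p up to 0.0994). The pseudokinase Trib3 also passed in both (adjusted p = 0.0162 and 0.0161). It was lost without sAB replicate 2 or AB replicate 2 (adjusted p up to 0.0582) in AB against sAB, without AB replicate 2 or sDB3 replicate 1 (adjusted p up to 0.0558) in AB against sDB3, and in both with no dim filter. Psat1 (0.13 ± 0.22), Phgdh (0.77 ± 0.39), Shmt2 (0.011 ± 0.074), Chac1 (0.19 ± 0.31) and Ddit3 (0.083 ± 0.21) did not pass in AB against sAB, with adjusted p-values of at least 0.198. Of these, Psat1 passed against sDB3 (0.75 ± 0.22, adjusted p = 0.0373), a call lost in 4 of 12 fits without 1 array (adjusted p up to 0.138).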
